A study of Mus musculus with 8 samples.

How the data were processed

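Gene expression was measured with 8 Affymetrix Mouse Genome 430 2.0 arrays, each hybridised with total RNA of cultured mouse CD4 T cells. Per the labels, naive CD4 T cells of the C57BL/6 strain were sorted by flow cytometry, grown on antibodies to CD3 and CD28 and kept for 48 h in a culture that drives Th17 differentiation. The cells were wildtype or deficient in RORγt, the nuclear receptor that directs Th17 differentiation, and received digoxin, a cardiac glycoside that inhibits the Na,K-ATPase, or DMSO. The dose of digoxin is not given in the sources used here. The 4 combinations of genotype and treatment had 2 arrays each, and every array was assigned from its title. The titles call the arrays of a group biological replicates without saying whether they came from separate animals or cultures, so p-values measure the spread between these arrays, which may be partly technical.

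Per the submitters' processing notes, probe intensities were summarised with RMA, which corrects background, normalises by quantiles and returns log2 values. The series' design text, also by the submitters, names GeneSpring GX 11.5 for the data analysis. The authors deposited log2 values for 45101 probe sets, 64 of them Affymetrix control probe sets. In the deposited log2 values the 2 wildtype DMSO arrays of each probe set summed to 0 within 1e-06, so the values are differences from the mean of these arrays; no label records this step. Differences between groups are unaffected by it, but no absolute expression level is left. That the logarithm has base 2 rests on RMA and on the binary precision of the deposited numbers, whose smallest step was that of single-precision numbers between 2 and 16. The same step gave a range for the lowest array level of each probe set before centring. That level lay between 2 and 4 for 5651 genes (31.1%), between 4 and 8 for 8735 genes (48.0%) and at 8 or above for 3807 genes (20.9%). On 2000 simulated probe sets this reading gave the right range for 99.2%. Array medians lay between -0.01 and 0.03 on the log2 scale. The number of arrays limits the precision.

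The table of probe annotations gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Probe sets with several symbols were not named or used, and those with none were tested only as a count. Leaving out controls, 34945 probe sets with 1 symbol remained, of which 34741 matched a gene of the GRCm38.p6 RefSeq table. That table served only for current symbols and for which genes neighbour each other, because no genome build is named in the sources used here. The gene encoding RORγt was not named by any single-gene probe set used here, so the targeted gene was not analysed here and its level did not check the genotype labels. For 9010 genes with more than 1 probe set, 1 was taken by the order of probe set suffix (_at, _a_at, _s_at, _x_at) and then identifier. This was the fallback fixed for values without absolute levels, in place of the probe set with the highest mean.

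All 18193 genes were tested with limma 3.58.1 in R 4.3.3. A linear model with the 4 group means was fitted to all 8 arrays together, which left 4 residual degrees of freedom, and eBayes with default settings added 5.8 prior degrees of freedom. The median standard deviation of a gene was 0.13 on the log2 scale, and the median standard error of a difference of the digoxin effects was 0.18. The 5 comparisons were RORγt deficiency in DMSO, digoxin in wildtype cells, digoxin in RORγt-deficient cells, the difference between these digoxin effects, and RORγt deficiency under digoxin. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and genes at an adjusted p under 0.05 were called. Values after ± are limma standard errors with n = 2 arrays per group unless given as SD. Arrays were simulated as independent normal values with limma's moderated SD of each of the 18193 genes. On these, the test of digoxin in wildtype cells recovered 31.3% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, and called 13 unchanged genes. The simulated difference between the digoxin effects recovered 2.99% of the genes at 0.5, 85.1% at 1 and 100% at 2, with 9 unchanged genes called. The simulation changed 67, 67 and 66 genes at these sizes, which eases the Benjamini-Hochberg threshold. Its shares are therefore no measure of what the data could detect where few genes change. In the data a difference of -2.49, that of Iyd, was not called (adjusted p = 0.0521).

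Named genes followed a rule fixed, like the design and the gene lists, before the data were examined. It took the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out symbols that are only clone or locus numbers. It added up to 4 members of each described list by smallest adjusted p, and the measured members of a fixed set of T helper genes (Il17a, Ccr6, Ccl20, Il1r1, Foxp3, Tbx21, Ifng, Gata3, Il4, Rora and Il2). With 2 arrays against 2, chance leaves 33.3% of genes without overlap. Genes outside the rule are named as such.

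The 29 gene lists covered Th17 effectors known to need RORγt, Th17 transcription factors, Th1, Th2, regulatory, follicular helper and naive T cell genes, and genes of T cell activation and immediate early response. They also covered the cell cycle, the unfolded protein and integrated stress responses, p53 targets, heat shock, Na,K-ATPase and ion transport, cholesterol synthesis, liver X receptor targets, glycolysis, interferon-stimulated genes, TGF-β targets, IL-6 and STAT3 targets, the circadian clock and ribosome biogenesis. Markers of B cells, myeloid cells, CD8 T cells, NK and innate lymphoid cells, gamma delta T cells, erythroid cells and basophils, and sex-linked genes completed them. Each list was tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 29 lists of a comparison. Calls within a list were counted over all genes and adjusted over the list alone.

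The fold changes of RORγt deficiency and of digoxin in wildtype cells share the wildtype DMSO arrays. Their correlation, covariance and same-sign share across genes were set beside 1000 simulations of unchanged groups against these arrays, and were computed again from disjoint arrays. Overlaps of calls were set beside 100 such simulations, in which the leading 22 and 191 genes by p-value stood for the called ones. Each split of the 2 control arrays leaves 1 array, so no split control group with replicates was possible.

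The alternatives chosen beforehand were testing every probe set, a common median, quantile normalisation of the deposited values, array weights, a fit of the compared groups alone, the replicate number as a block, a 2-fold threshold, and leaving out each array in turn. A filter on dim probe sets and an intensity trend, also chosen beforehand, need absolute levels and were not run on the centred values. In their place, after the data were seen, a choice of probe set, a filter at an estimated mean level of at least 4, which left out exactly the genes whose lowest array level lay between 2 and 4, and a trend used the levels recovered from the binary step. The estimated mean level was a fixed value for the range of the lowest array level plus the distance of the gene's mean from its lowest array. Within a range it therefore followed the gene's own spread between arrays. A comparison of RORγt-deficient cells in DMSO with wildtype cells in digoxin, a list of T cell lineage genes and the control probe sets for RNA quality were also added afterwards.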

Results

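The data comprised log2 expression values of 18193 genes in CD4 T cells kept for 48 h in Th17 culture, in 4 groups of 2 arrays: wildtype cells in DMSO, wildtype cells in digoxin, RORγt-deficient cells in DMSO and RORγt-deficient cells in digoxin. Every value was a difference from the mean of the wildtype DMSO arrays, so that group stood at 0 for each gene. The SD over genes was 0.09 on each wildtype DMSO array and from 0.17 to 0.28 on the other 6. Between the 2 arrays of a group, the SD of the differences was 0.18 in wildtype DMSO, 0.24 in wildtype digoxin, 0.22 in RORγt-deficient DMSO and 0.21 in RORγt-deficient digoxin. The leading principal component held 40.0% of the variance and the next 16.4%. Arrays of a group also stood apart on the leading component, with scores of -13.3 and -19.9 in wildtype DMSO, -11.1 and 9.55 in wildtype digoxin, -3.43 and 14.8 in RORγt-deficient DMSO and 5.15 and 18.3 in RORγt-deficient digoxin. The gene encoding RORγt was not analysed here, so the genotype labels were not checked on the targeted gene.

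RORγt-deficient cells were first compared with wildtype cells in DMSO, which asks what the receptor does in Th17 culture. Il17a, the signature cytokine gene of Th17 cells, was 4.31-fold lower in the deficient cells (log2 change -2.11 ± 0.12, SE, n = 2 arrays per group, adjusted p = 0.00011). The largest fall was that of Iyd, the iodotyrosine deiodinase, at 11.1-fold (-3.47 ± 0.19). Ppp1r14c, an inhibitor of protein phosphatase 1, fell 4.26-fold (-2.09 ± 0.14), and Nupr1, a stress-induced transcriptional regulator, 3.22-fold (-1.69 ± 0.14). The largest rises were those of Plac8, which encodes a small cysteine-rich protein, at 3.54-fold (1.82 ± 0.12), and Slfn1, a Schlafen family regulator of T cell growth, at 3.37-fold (1.75 ± 0.13). The immunoregulatory cytokine gene Il10 rose 2.72-fold (1.45 ± 0.14). In all, limma called 191 of 18193 genes, 51 higher and 140 lower, of which 47 changed at least 2-fold, and 1879 genes had an unadjusted p under 0.05.

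In RORγt deficiency Klrd1, which encodes CD94, rose by 1.38 ± 0.11, Nkg7, which encodes a granule membrane protein, by 1.29 ± 0.11, Klrk1, which encodes NKG2D, by 1.06 ± 0.16, and Gzmb, which encodes granzyme B, by 1.05 ± 0.11. Genes of the calcium-binding proteins S100a6 and S100a4 rose by 1.58 ± 0.14 and 1.25 ± 0.17, and Tnfrsf23, which encodes a decoy receptor for TRAIL, by 1.13 ± 0.17. Among the falls were Hspa1a (-1.75 ± 0.26) and Hspa1b (-1.66 ± 0.24), which encode the near-identical inducible forms of Hsp70, so their values are not independent. Gcnt2, a branching glycosyltransferase, stood at -1.43 ± 0.18, Prr29 at -1.36 ± 0.17, Sgo2a, a protector of centromeric cohesion, at -1.32 ± 0.20, and Nebl, an actin-binding protein, at -1.22 ± 0.18. All 4 of these were called, at adjusted p from 0.00702 to 0.0146. Of the 35 named called genes, 14 had other probe sets, and in 6 of these another one differed by over 1.5 times. The other probe sets stood at 0.01 for Aurka, -0.36 for Bub1 and -0.13 for Slfn1, and ranged from -1.45 to 0.01 for Gcnt2, from -1.46 to -0.43 for Nebl and from 0.23 to 0.37 for Igfbp4.

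Among the 11 T helper genes fixed in advance and measured here, Il17a was the only one called for RORγt deficiency. Further Th17 effectors of the fixed set had no single-gene probe set used here. Ccr6, the chemokine receptor of Th17 cells, stood at -0.71 ± 0.16 (adjusted p = 0.087), its ligand gene Ccl20 at -0.30 ± 0.14 and Il1r1, an interleukin 1 receptor gene, at -0.19 ± 0.11. Il2, the T cell growth factor gene, stood at -0.50 ± 0.11 (adjusted p = 0.0693). Foxp3 (0.08 ± 0.15), Tbx21 (0.32 ± 0.10) and Gata3 (0.24 ± 0.14), the lineage regulators of regulatory, Th1 and Th2 cells, were not called. Ifng (-0.06 ± 0.19), Il4 (0.09 ± 0.12) and Rora, which encodes a related nuclear receptor (0.17 ± 0.14), were not called either.

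Cell cycle genes were lower as a group in RORγt-deficient cells, with a median of -0.59 over 20 measured members. Of these, 8 fell and 13 were called when adjusted over the list alone, all lower. Bub1, a spindle checkpoint kinase, fell by 1.18 on the log2 scale, Mki67, the proliferation marker Ki-67, by 1.11, Ccnb2, cyclin B2, by 1.05, and Aurka, a mitotic kinase, by 0.87. The camera adjusted p was 2.41e-16, and the adjusted p = 0.118 with an estimated correlation. Targets of p53 were higher, with a median of 0.31 over 13 members, of which only Ccng1, cyclin G1, was called (0.60 ± 0.11), and 8 when adjusted over the list alone. Their camera adjusted p was 6.7e-09, and the adjusted p = 0.0884 with an estimated correlation. Genes of naive T cells had a median of 0.22 over 12 members, with Igfbp4 (0.65 ± 0.11) and the lymph node homing receptor Ccr7 (0.58 ± 0.10) called, Igfbp4 by 1 of its 6 probe sets, and 3 when adjusted over the list alone. Their camera adjusted p was 4.11e-06, and the adjusted p = 0.0884 with an estimated correlation.

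Th17 effectors had a median of -0.19 over 11 members in RORγt deficiency, and Il17a and the proprotein convertase gene Furin (-1.0 ± 0.17) fell. Adjusted over the list alone, 4 members were lower and 2 higher. The camera adjusted p was 0.0017, and the adjusted p = 0.373 with an estimated correlation. The unfolded protein and integrated stress response list had a median of -0.26 over 16 members. The amino acid stress genes Asns (-0.80 ± 0.10), Chac1 (-0.90 ± 0.13) and Trib3 (-0.74 ± 0.11) fell, and 5 members were called when adjusted over the list alone. The camera adjusted p was 7.68e-05, and the adjusted p = 0.0884 with an estimated correlation. The clock list had a median of -0.16 over 14 members. Nr1d2, which encodes the repressor REV-ERBβ, fell by 0.70 on the log2 scale, and 3 members were called when adjusted over the list alone (camera adjusted p = 0.00493, and adjusted p = 0.136 with an estimated correlation). In the heat shock list the median was -0.13 over 12 members, and Hspa1a and Hspa1b were the 2 called, as they were when adjusted over the list alone (camera adjusted p = 0.000868, and adjusted p = 0.399 with an estimated correlation). Ribosome biogenesis genes had a median of -0.10 over 16 members, with 0 called by limma, 2 at an adjusted p over the list alone and a camera adjusted p of 0.00866 (adjusted p = 0.523 with an estimated correlation).

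Of the marker lists of other lymphocytes, those of NK and innate cells and of CD8 T cells passed camera in RORγt deficiency. The NK and innate list had a median of 0.30 over 8 members, of which Klrd1 and Klrc1, which encodes NKG2A (0.96 ± 0.18), rose, and 2 were called when adjusted over the list alone. Its camera adjusted p was 7.68e-05, and the adjusted p = 0.118 with an estimated correlation. The CD8 T cell list had a median of 0.24 over 8 members, of which Klrk1 rose, and 1 was called when adjusted over the list alone (camera adjusted p = 0.000901, and adjusted p = 0.118 with an estimated correlation). The receptors Klrd1, Klrc1 and Klrk1 are also known on activated T cells. The defining genes Cd8a (0.22 ± 0.13), Cd8b1 (0.23 ± 0.13) and, for NK cells, Ncr1 (0.00 ± 0.14) were not called. The remaining 19 lists did not pass camera, with medians from -0.09 to 0.13 and adjusted p from 0.0883 upward. They were Th17 transcription factors, Th1, Th2, regulatory, follicular helper, activation, immediate early, Na,K-ATPase, cholesterol, liver X receptor, glycolysis, interferon, TGF-β, IL-6 and STAT3 genes, and B cell, myeloid, gamma delta T cell, erythroid and basophil markers and sex-linked genes. Single members called in these were Il12rb2 (0.72 ± 0.13), an interleukin 12 receptor gene, and Zbp1 (0.62 ± 0.12), a nucleic acid sensor gene.

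The count for RORγt deficiency rested on every array of the comparison. It was 47 without wildtype DMSO array 1, 17 without wildtype DMSO array 2, 56 without RORγt-deficient DMSO array 1 and 28 without RORγt-deficient DMSO array 2, and 95 with only the compared groups in the fit. Quantile normalisation of the centred values, which widens the wildtype DMSO arrays to the spread of the others, left 4 genes, Iyd, Il17a, Ppp1r14c and Nkg7. Plac8, Slfn1, S100a6, Il10, Klrd1, Nkg7, Iyd, Il17a, Ppp1r14c and Nupr1 were called without each array in turn, and 25 of the 35 named called genes were not. Without wildtype DMSO array 2 the Th17 effectors (camera adjusted p = 0.0518) and ribosome biogenesis (0.197) lost their calls, as did ribosome biogenesis without RORγt-deficient DMSO array 2 (0.338) and the clock list without wildtype DMSO array 1 (0.0503). Of the 10 lists that passed camera, 7 passed fry, and Th17 effectors, heat shock and ribosome biogenesis did not (fry adjusted p = 0.055, 0.109 and 0.273). The regulatory T cell list passed fry (adjusted p = 0.0087) but not camera (0.0883), with a median of 0.04 over 15 members, 0 called by limma and 3 higher when adjusted over the list alone, Gpr83 (0.46), Nt5e (0.45) and Izumo1r (0.43), named after their values were seen.

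**Figure D1:**
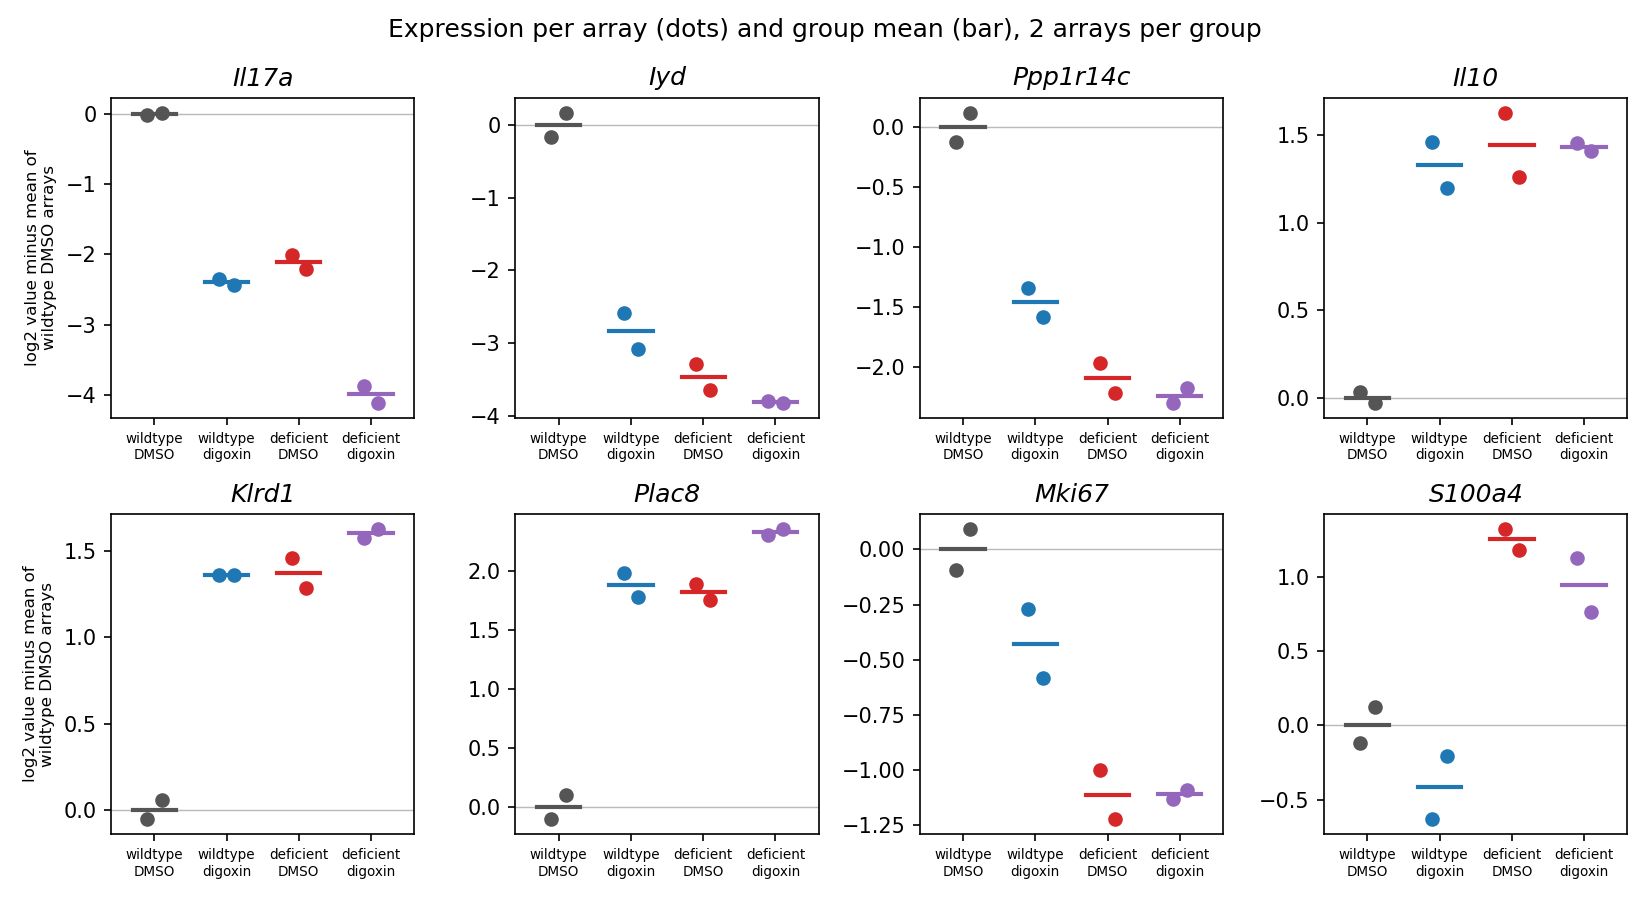
Log2 expression of Il17a, Iyd, Ppp1r14c, Il10, Klrd1, Plac8, Mki67 and S100a4 on each array (dots) as a difference from the mean of the wildtype DMSO arrays, with the mean of the 2 arrays of each group as a bar; each panel has its own vertical axis. Il17a lay at -2.39 in wildtype digoxin, -2.11 in RORγt-deficient DMSO and -3.99 in RORγt-deficient digoxin.

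Digoxin in wildtype cells, the test of the drug where RORγt is present, was accompanied by 5.26-fold lower Il17a (-2.39 ± 0.12, adjusted p = 6.5e-05) and 7.16-fold lower Iyd (-2.84 ± 0.19). Hspa1b fell by 1.62 on the log2 scale, Igfbp7, a secreted insulin-like growth factor binding protein, by 1.5, Ppp1r14c by 1.46, Nupr1 by 1.19 and Gap43, a growth-associated protein of neurons, by 1.14. Csf2, the gene of the cytokine GM-CSF, fell 1.79-fold (-0.84 ± 0.12), and Ramp1, a subunit of the receptor for calcitonin gene-related peptide, 1.74-fold (-0.80 ± 0.10). Limma called 22 genes, 13 higher and 9 lower, of which 14 changed at least 2-fold, and 1272 had an unadjusted p under 0.05. The other probe sets stood at -0.24 and 0.17 for Igfbp7, at -0.20 and 0.08 for Ramp1 and at 0.20 for Slfn1.

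The largest rise under digoxin was that of Plac8, 3.67-fold (1.88 ± 0.12). Klrd1 (1.36 ± 0.11) and Il10 (1.33 ± 0.14) rose 2.57-fold and 2.51-fold, and Gzmb 1.78-fold (0.83 ± 0.11). Moxd1, a monooxygenase-like gene, rose by 1.36 ± 0.14, Gpr15, a homing receptor of T cells in the large intestine, by 1.21 ± 0.12, and Ifitm1, an interferon-induced membrane protein, by 1.16 ± 0.11. Tafa3, a secreted chemokine-like protein, Serpinb5, known as maspin, and Slfn1 rose by 1.00 ± 0.10, 0.98 ± 0.10 and 0.93 ± 0.13. The other 3 called rises, outside the rule for named genes, were Nkg7 (0.82), Cd86, a costimulatory ligand gene (0.78), and Ecm1 (0.71). Ccr6 stood at -0.85 ± 0.16 (adjusted p = 0.121), Ccl20 at -0.36 ± 0.14, Il1r1 at -0.21 ± 0.11 and Il2 at -0.64 ± 0.11 (adjusted p = 0.0643), none of them called. Foxp3 (0.00 ± 0.15), Tbx21 (0.35 ± 0.10), Ifng (-0.03 ± 0.19), Gata3 (-0.06 ± 0.14), Il4 (-0.10 ± 0.12) and Rora (0.02 ± 0.14) were not called.

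Th17 effectors had a median of -0.21 over 11 members under digoxin in wildtype cells, with Il17a called and 3 when adjusted over the list alone, all lower. Furin stood at -1.11 ± 0.17 (adjusted p = 0.0538). The camera adjusted p was 9.17e-05, and the adjusted p = 0.313 with an estimated correlation. The unfolded protein and integrated stress list had a median of -0.29 over 16 members, with 0 called by limma over all genes and 5 lower when adjusted over the list alone; Chac1 stood at -0.59 ± 0.13 and Trib3 at -0.47 ± 0.11. Its camera adjusted p was 1.2e-05, and the adjusted p = 0.162 with an estimated correlation. Clock genes had a median of -0.11 over 14 members, with 0 called over all genes and 4 lower when adjusted over the list alone, Nr1d2 at -0.69 ± 0.11 and Cry1, a clock repressor, at -0.59 ± 0.18 (camera adjusted p = 0.00425, and adjusted p = 0.196 with an estimated correlation). In the heat shock list, median -0.15 over 12 members, Hspa1b was called, and 2 when adjusted over the list alone; Hspa1a stood at -1.46 ± 0.26 (camera adjusted p = 0.0011, and adjusted p = 0.435 with an estimated correlation).

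The marker lists of NK and innate cells and of CD8 T cells passed camera under digoxin in wildtype cells, while those of B cells (camera adjusted p = 0.168) and gamma delta T cells (0.185) did not. The NK and innate list had a median of 0.24 over 8 members, with Klrd1 called and 2 when adjusted over the list alone, and Klrc1 at 0.78 ± 0.18 (camera adjusted p = 0.000472, and adjusted p = 0.196 with an estimated correlation). The CD8 list had a median of 0.21 over 8 members, with 0 called over all genes, 2 when adjusted over the list alone and Klrk1 at 1.03 ± 0.16 (camera adjusted p = 0.00284, and adjusted p = 0.196 with an estimated correlation). Cd8a stood at 0.09 ± 0.13 and Cd8b1 at 0.03 ± 0.13, and Ncr1 at 0.10 ± 0.14. Th1 genes had a median of 0.03 and a mean of 0.16 over 12 members, with 0 called and 5 higher when adjusted over the list alone, among them Cxcr3, a chemokine receptor gene (0.53 ± 0.11), and Hlx, a transcription factor gene (0.63 ± 0.15). Their camera adjusted p was 0.0298, and the adjusted p = 0.25 with an estimated correlation. Naive T cell genes had a median of 0.08 over 12 members with 0 called and 1 when adjusted over the list alone, Igfbp4 at 0.53 ± 0.11 (camera adjusted p = 0.00945, and adjusted p = 0.196 with an estimated correlation). Cell cycle genes had a median of -0.10 over 20 members with 0 called on either count, Mki67 at -0.43 ± 0.14 (camera adjusted p = 0.00798, and adjusted p = 0.466 with an estimated correlation).

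The genes of the Na,K-ATPase, the classical target of digoxin, and of related ion transport were not called in wildtype cells, with a median of 0.11 over 10 members and the calcium exchanger gene Slc8a1 at 0.43 ± 0.18. The p53 targets had a median of -0.09 over 13 members and were not called. The other 18 uncalled lists, which covered Th17 transcription factors, Th2, regulatory and follicular helper genes, activation, immediate early and ribosome biogenesis genes, cholesterol, liver X receptor, glycolysis, interferon, TGF-β and IL-6 and STAT3 genes and B cell, myeloid, gamma delta, erythroid and basophil and sex-linked markers, had medians from -0.15 to 0.21. The Th2 list's median (-0.06) and mean (0.04) differed in sign.

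The count of 22 for digoxin was 6 without wildtype DMSO array 1, 7 without wildtype DMSO array 2, 12 without wildtype digoxin array 2, 9 with only the compared groups in the fit, 35 with array weights, 49 with a variance trend on the recovered level and 3 after quantile normalisation, Il17a, Iyd and Igfbp7, all lower. Plac8, Klrd1, Iyd, Il17a and Igfbp7 were called without each array in turn, and 14 of the 19 genes named by the rule were not. Cell cycle genes lost their call without wildtype DMSO array 2 (camera adjusted p = 0.423) and without wildtype digoxin array 2 (0.574), Th1 genes without wildtype DMSO array 1 (0.0693, with a median of -0.00284) and without wildtype digoxin array 1 (0.108), and naive genes without wildtype digoxin array 1 (0.13). By fry, cell cycle, heat shock, CD8 and NK lists did not pass (adjusted p = 0.4, 0.207, 0.109 and 0.0664), and the other 5 did. The regulatory T cell list passed fry (adjusted p = 0.016) but not camera (0.11), with a median of 0.00 over 15 members, 0 called by limma and 4 higher when adjusted over the list alone, Entpd1 (0.66), Izumo1r (0.43), Gpr83 (0.42) and Nt5e (0.37), named after their values were seen.

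The series asks whether digoxin acts on the genes that depend on RORγt. Of the 22 genes called for digoxin in wildtype cells, 22 had the same sign in RORγt deficiency, and 19 were called in both, 11 higher, such as Plac8, Il10, Klrd1, Nkg7 and Gzmb, and 8 lower, such as Il17a, Iyd, Ppp1r14c, Hspa1b and Nupr1. Both comparisons use the wildtype DMSO arrays, so the lists are not independent. In 100 simulations of unchanged groups against shared controls, the 22 leading digoxin genes had the same sign in 20.7 cases on average (17 to 22), 6.37 of them (2 to 12) were also among the 191 leading deficiency genes, and 0.07 genes (0 to 1) were called in both. Adjusted p-values call few genes when no group changes, so the last number was bound to be low. Independent lists would share 0.0364 higher and 0.0693 lower genes, a value that leaves out the shared arrays. Of the 191 genes called for RORγt deficiency, 172 were not called for digoxin, S100a6, Mki67, Bub1 and Sgo2a among them. Csf2, Serpinb5 and Tafa3 were called for digoxin alone, with values in RORγt deficiency of -0.52, 0.34 and 0.52. Another probe set of Serpinb5, of higher recovered level, rose in RORγt deficiency as well (0.69, adjusted p = 0.0204 over all probe sets). The sign under digoxin was the same for 187 of the 191, against 177 (168 to 184) simulated with no change, with a median of 0.34 in that direction against 0.83 for deficiency itself. These genes were chosen for their effect in RORγt deficiency, which enlarges the 0.83, and error of the shared arrays enters both medians. S100a4 was of opposite sign, at 1.25 for deficiency and -0.42 under digoxin.

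Across all 18193 genes, which are not independent replicates, the fold changes of RORγt deficiency and digoxin had a Pearson r of 0.671 and a Spearman rho of 0.630, and 72.7% had the same sign. Unchanged groups simulated against the shared wildtype DMSO arrays gave 0.50, 0.477 and 66.7%. The covariance was 0.0237 against 0.00938 simulated, an excess of 0.0143. From disjoint arrays, 4 assignments were run, each with a RORγt-deficient DMSO array and the wildtype digoxin array of the other replicate number. The covariance was 0.00875, 0.0161, 0.0117 and 0.000957, with a mean of 0.00938. Assignments with equal replicate numbers were not run. Deviations from the group means correlated at 0.454 by number between these groups, so covariances of unlike numbers may be too low. Disjoint arrays share no control, so unchanged groups with independent arrays would give no covariance on average there. The simulated value, equal to the mean of 0.00938 by coincidence, is no reference for it. Part of the excess may come from the shared arrays, because the control group could not be split with replicates.

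**Figure D2:**
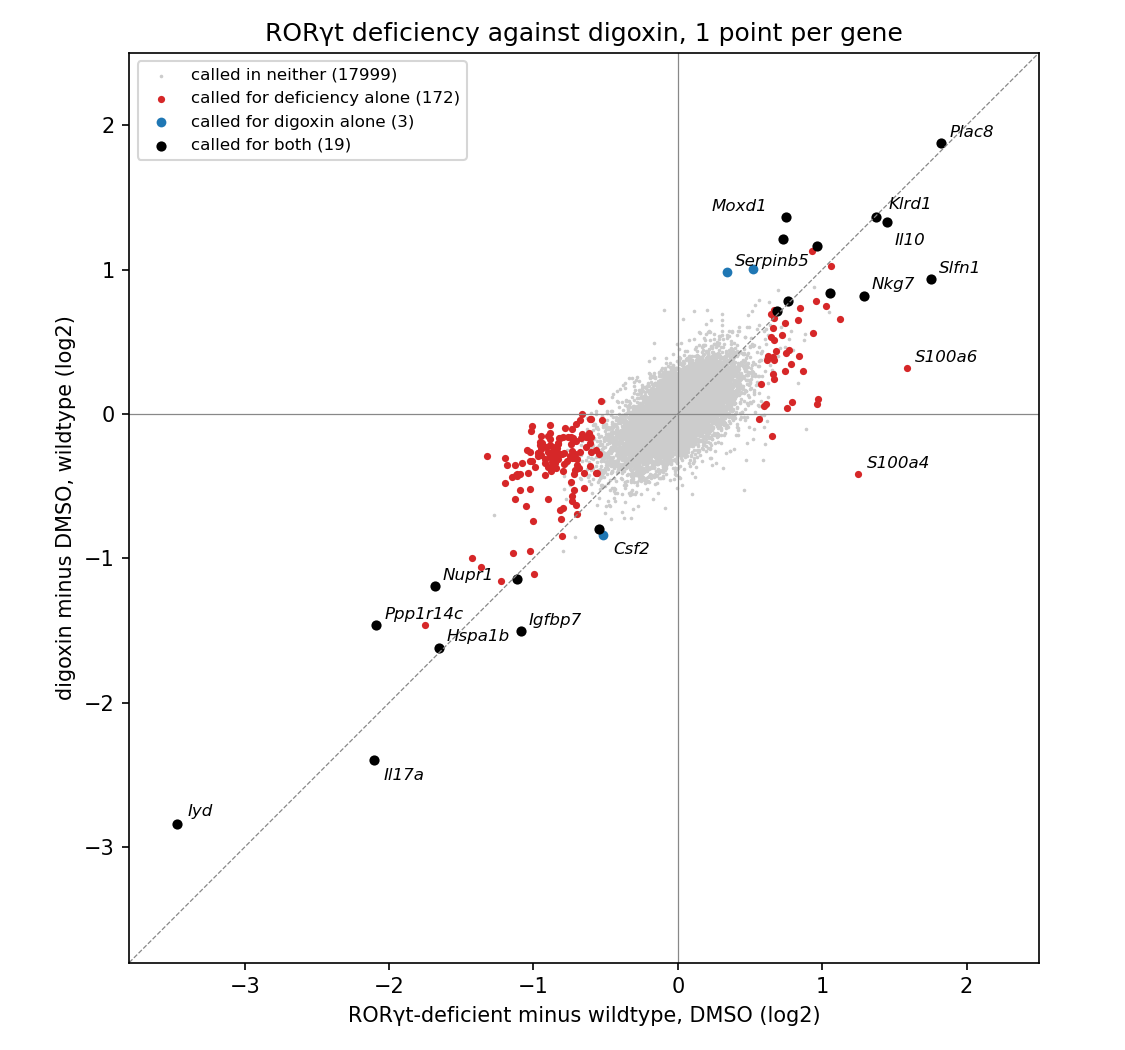
Log2 fold change of digoxin in wildtype cells (vertical) against that of RORγt deficiency in DMSO (horizontal), 1 dot per gene, with genes called in both comparisons in black, for deficiency alone in red, for digoxin alone in blue, and the line of equal change dashed. The 19 genes called in both lie in the quadrants of equal sign, from Iyd at -3.47 and -2.84 to Plac8 at 1.82 and 1.88.

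In RORγt-deficient cells Il17a was a further 3.69-fold lower with digoxin (-1.88 ± 0.12, adjusted p = 0.000634), from -2.11 ± 0.14 (SD, n = 2) in DMSO to -3.99 ± 0.18 in digoxin relative to wildtype DMSO. Il17a was the 1 gene called by limma, and 639 had an unadjusted p under 0.05. Among Th17 effectors the interleukin gene Il24 stood at -0.33 ± 0.11, Ccr6 at -0.41 ± 0.16 and Furin at -0.40 ± 0.17, and the list's median was -0.14 over 11 members, with 1 called on either count. Its camera adjusted p was 6.37e-05, the adjusted p = 0.905 with an estimated correlation, and fry's 0.455. The other 28 lists did not pass, with medians from -0.09 to 0.09; in 7 of them median, mean and direction of the test differed in sign. Immediate early genes had 1 member called when adjusted over the list alone, Klf4 (-0.62 ± 0.14). The call of Il17a ended after quantile normalisation (-0.68, adjusted p = 1) and with a variance trend on the recovered level (adjusted p = 0.0913). Within its range of lowest level, the recovered level of Il17a was raised by its own fall, so that trend does not isolate a dependence on intensity. Quantile normalisation here ranked differences from wildtype DMSO, not expression levels. Il17a lay far below most genes on the arrays of both groups, which by construction narrows its change. The Th17 effectors lost their camera call without RORγt-deficient DMSO array 1 (median -0.12).

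The digoxin effect on Iyd was -2.84 in wildtype and -0.35 in RORγt-deficient cells, and their difference of -2.49 ± 0.26 was the nearest to a call (adjusted p = 0.0521). Plac8 differed by 1.37, Il10 by 1.34, Ppp1r14c by -1.31 and Klrd1 by 1.13, while Il17a differed by -0.51 ± 0.17 (adjusted p = 1), or by -1.34 ± 0.27 after quantile normalisation (adjusted p = 1). By construction that step narrowed the fall of Il17a in RORγt-deficient cells. Limma called 0 of 18193 genes for this difference, and 562 had an unadjusted p under 0.05. Without wildtype digoxin array 1, and with array weights, it called 1, Iyd (adjusted p = 0.0162 and 0.0462). The 22 genes called for digoxin in wildtype cells had the same sign in RORγt-deficient cells in 21 cases, the exception being Il10 (-0.01), and the effect was smaller in 22. Their median effect was 0.26 in RORγt-deficient and 1.18 in wildtype cells. In RORγt-deficient cells 11 had an unadjusted p under 0.05 and 7 passed when adjusted over these 22. For the difference, 21 passed when adjusted over these 22, but they were chosen for their effect in wildtype cells, which enlarges the difference. Their lowest array level before centring was at least 4 in all 22.

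By camera 7 lists differed between the digoxin effects. Wildtype minus RORγt-deficient medians were -0.25 for unfolded protein and integrated stress genes (adjusted p = 0.00154, and adjusted p = 0.264 with an estimated correlation), -0.15 for cell cycle genes (0.00334, and adjusted p = 0.61 with an estimated correlation) and -0.12 for clock genes (0.00993, and adjusted p = 0.264 with an estimated correlation). They were -0.13 for heat shock genes (0.00993, and adjusted p = 0.61 with an estimated correlation) and 0.10 for naive T cell genes (0.00993, and adjusted p = 0.264 with an estimated correlation). The CD8 and NK lists stood at 0.16 and 0.18 (both 0.00334, and adjusted p = 0.264 with an estimated correlation). Single genes called when adjusted over the list alone were 2 in the heat shock and 2 in the NK list and 0 in the other 5. Fry called 0 lists at an adjusted p, and its smallest was 0.0525, for naive and stress genes. The other 22 lists did not pass, with medians from -0.18 to 0.18; in 4 of them median, mean and direction of the test differed in sign. The stress gene list passed camera without each array in turn. Without wildtype digoxin array 2 the cell cycle (camera adjusted p = 0.279), heat shock (0.279), clock, CD8 and NK lists (0.0562 each) did not, and without wildtype digoxin array 1 the naive list did not (0.124). The cell cycle list was also lost without wildtype DMSO array 2 (0.231), and the clock list without wildtype DMSO array 1 (0.0928), RORγt-deficient DMSO array 2 (0.0933) or RORγt-deficient digoxin array 2 (0.0713). Naive and heat shock genes were lost without RORγt-deficient DMSO array 2 (0.0507 and 0.24) or RORγt-deficient digoxin array 1 (0.0626 and 0.343), as were NK genes without the latter (0.232) and heat shock genes with probe sets chosen by recovered level (0.0571).

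**Figure D3:**
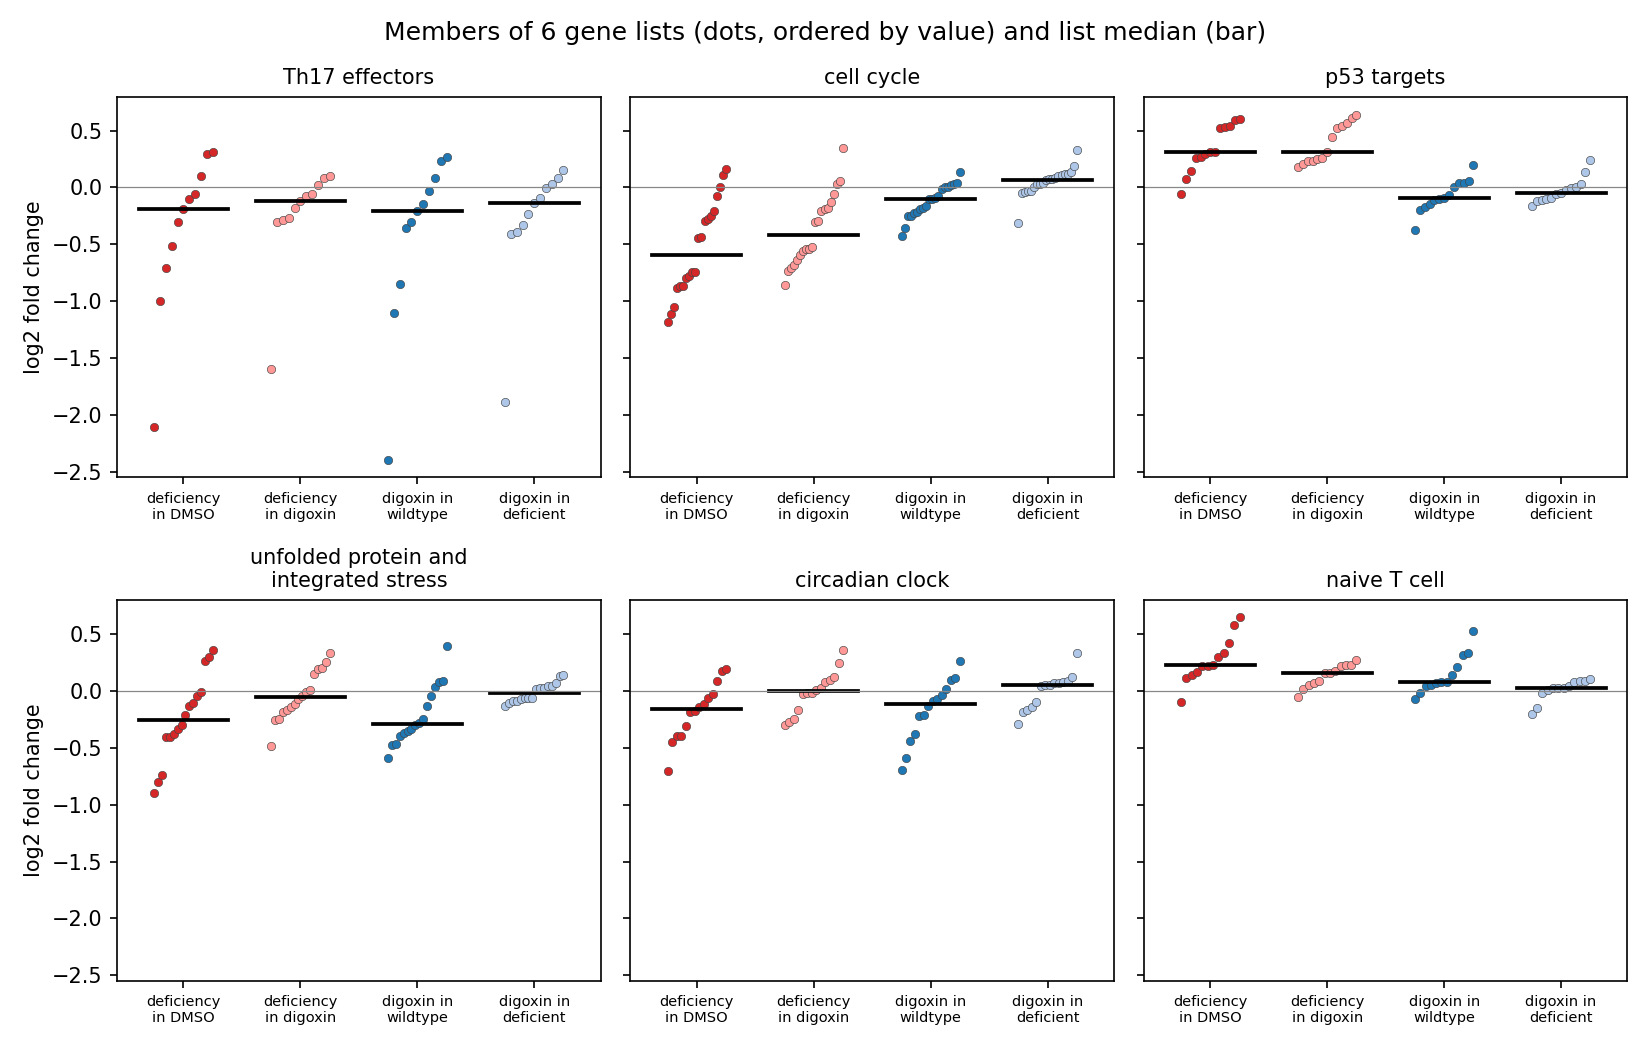
Log2 fold changes of the measured members of 6 gene lists (dots, ordered by value) and their median (bar) for RORγt deficiency in DMSO and in digoxin and for digoxin in wildtype and in RORγt-deficient cells. Medians of the cell cycle list were -0.59, -0.42, -0.10 and 0.07 in this order, and those of the p53 targets 0.31, 0.31, -0.09 and -0.05.

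Under digoxin, Il17a was 3.03-fold lower in RORγt-deficient than in wildtype cells (-1.60 ± 0.12, adjusted p = 0.00299), and it was the 1 gene called by limma, with 1003 at an unadjusted p under 0.05. Cell cycle genes had a median of -0.42 over 20 members, with 0 called over all genes and 10 lower when adjusted over the list alone, such as Bub1 (-0.85 ± 0.14), Ccnb2 (-0.70 ± 0.12), the apoptosis inhibitor and mitotic gene Birc5 (-0.74 ± 0.13) and the kinase gene Cdk1 (-0.56 ± 0.11). Their camera adjusted p was 2.34e-15, and the adjusted p = 0.261 with an estimated correlation. All 13 measured p53 targets were above 0, with a median of 0.31, 0 called over all genes and 7 higher when adjusted over the list alone. Among them were Phlda3, an inhibitor of AKT (0.61 ± 0.11), the RNA-binding protein gene Zmat3 (0.57 ± 0.11), Ccng1 (0.54 ± 0.11) and Bbc3, which encodes the cell death protein PUMA (0.63 ± 0.15). Their camera adjusted p was 3.22e-15, and the adjusted p = 0.0746 with an estimated correlation. Naive T cell genes had a median of 0.16 over 12 members with 0 called on either count (camera adjusted p = 0.00636, and adjusted p = 0.261 with an estimated correlation). Th17 effectors had a median of -0.12 over 11 members, with Il17a called on either count (camera adjusted p = 0.00472, and adjusted p = 0.652 with an estimated correlation). The other 25 lists did not pass, with medians from -0.08 to 0.15; in 2 of them median, mean and direction of the test differed in sign. Fry passed the naive and p53 lists, but not the cell cycle (adjusted p = 0.0812) or the Th17 effectors (0.309).

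The call of Il17a for RORγt deficiency under digoxin ended without RORγt-deficient digoxin array 2 (-1.47) and after quantile normalisation (-0.77, adjusted p = 1). The latter ranks differences from wildtype DMSO and by construction narrows the change of so low a gene. With a variance trend on the recovered level limma called 28 genes, and without wildtype digoxin array 1 it called 2, Il17a and S100a6, an S100 calcium-binding protein. Th17 effectors lost their camera call without wildtype digoxin array 1 (adjusted p = 0.267) or RORγt-deficient digoxin array 2 (0.0785), and naive genes without wildtype digoxin array 2 (0.135).

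Genes that lie near the gene encoding RORγt were tested for an excess of calls for RORγt deficiency, because knockout alleles can carry flanking sequence of another strain. Within 10 Mb, 5 of 318 tested genes were called (1.57%): Cks1b, a cell cycle kinase subunit, Ecm1, S100a4, S100a6 and Txnip, a thioredoxin inhibitor. Elsewhere 186 of 17714 were called (1.05%). The odds ratio was 1.51 (95% interval 0.48 to 3.61, Fisher's exact test, two-sided, p = 0.395), and it was 2.12 with probe sets chosen by recovered level (p = 0.0618) and 3.49 without wildtype DMSO array 2 (p = 0.261).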

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

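The tests of shared control arrays, of chance or a state of the control cultures, of single arrays, of scaling and of RNA quality were chosen after the results had been seen, and the T cell lineage genes and the test of digoxin acting regardless of RORγt were added later but before their values were known.

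Digoxin in wildtype cells and RORγt deficiency moved 19 genes the same way, out of 22 and 191 called, with Il17a, Iyd and Ppp1r14c lower and Plac8, Il10 and Klrd1 higher. For the 22 genes called under digoxin, chance error or a state of the wildtype DMSO arrays as the whole cause of the digoxin changes was argued against by the RORγt-deficient cells, a comparison without those arrays, where 21 of the 22 had the wildtype direction, by a median of 0.26 against 1.18, and 11 had an unadjusted p under 0.05. The 22 genes may move together and are not independent cases, and no share over all genes was set beside the 21. For the changes of these genes in RORγt deficiency, chance error was argued against by the 19 of 22 that were among the 191 called there. In simulations of unchanged groups, 2 to 12 of the 22 leading digoxin genes were among the 191 leading deficiency genes. A state of the wildtype DMSO cultures stays open, because 16 of the 22 had the wildtype digoxin direction in RORγt deficiency under digoxin (median 0.24). That comparison is also without those arrays, and digoxin itself could have reduced the difference. Beyond the 22, shared arrays and a common effect cannot be told apart by the assignments run, since with disjoint arrays 83, 96, 80 and 51% of the top 100 genes of RORγt deficiency had the same sign under digoxin, and each of these 4 values rests on single arrays. These assignments joined RORγt-deficient DMSO and wildtype digoxin arrays of unlike replicate number, and those of equal number were not run. Digoxin may act on these genes through RORγt, but this and an action regardless of RORγt cannot be told apart either. Over 100 genes picked on 1 wildtype pair of arrays, the effects in the other wildtype and the other RORγt-deficient pair were compared. Their median difference was 0.265 (95% bootstrap interval over genes 0.192 to 0.366) in one assignment of arrays and -0.202 (-0.315 to -0.06) in the other. With the wildtype DMSO arrays exchanged, an assignment added afterwards, it was 0.433 (0.297 to 0.523) and 0.166 (0.0645 to 0.377), above 0 in both. Each value rests on single arrays and genes are not independent replicates, so the intervals leave out the spread between arrays.

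Il17a fell under digoxin in cells without RORγt as well, by 1.88 ± 0.12 on the log2 scale. A single aberrant array was argued against by the smallest fall with an array left out, -1.76 (adjusted p = 0.0259; over all settings run the adjusted p ranged from 8.34e-05 to 1). Whether scaling between arrays, which acts on genes of a level alike, contributed was not decided. Of 8734 genes with their lowest array level in the same range as Il17a, 0 fell by at least 50% as much (lowest value -0.87, Gap43). RMA had already normalised the arrays by quantiles, so this outcome was largely fixed beforehand. That range also held 48.0% of all genes, so it matched the level of Il17a only coarsely. Quantile normalisation of the deposited values, which gives genes of equal rank the same value on every array, left -0.68 ± 0.19 and ended the call. Fewer T cells among the cells harvested were argued against by 12 measured T cell lineage genes, whose median was 0.0137 (range -0.33 to 0.09). That digoxin may lower Il17a partly without RORγt remains a hypothesis, and residual activity of the deficient allele stays open because the targeted gene was not analysed here.

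Cell cycle genes were lower in RORγt-deficient cells, with a median of -0.59 over 20 members in DMSO, and p53 targets were higher, with a median of 0.31, by camera at its preset correlation. With an estimated correlation the adjusted p was 0.118 for the cell cycle list and 0.0884 for the p53 targets, and neither passed. A single aberrant array was argued against by the smallest median fall with an array left out, -0.47 (camera adjusted p = 4.61e-12). Loss of 5′ ends of the RNA in the deficient cells was argued against by the 3′ minus 5′ difference of the Gapdh and actin controls, which was lower in them, at -0.0655 (SD of such a difference 0.0327), and fewer T cells by the lineage genes, with a median of 0.0817 (range -0.24 to 0.43, SD 0.198). Slower growth of cells without RORγt may account for the pattern as a hypothesis, and a difference in culture timing or cell density stays open as untested.

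The digoxin effect differed between the genotypes in 7 gene lists by camera, given as wildtype minus RORγt-deficient medians on the log2 scale. Unfolded protein and integrated stress genes stood at -0.25, cell cycle genes at -0.15, heat shock genes at -0.13 and clock genes at -0.12. Naive T cell genes stood at 0.10, CD8 T cell markers at 0.16 and NK and innate markers at 0.18. With an estimated correlation the adjusted p was 0.264 for 5 of these lists and 0.61 for the cell cycle and heat shock lists, and fry called 0 of them. Of 9160 probe sets without a gene name, which entered no comparison by gene, limma called 18 for RORγt deficiency in DMSO, 11 higher and 7 lower, and 6 for digoxin in wildtype cells, 4 higher and 2 lower.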

How the results depend on the processing

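Settings built on recovered levels and the exchanged replicate numbers were chosen after the data had been seen. No called gene named by the rule, camera direction of a called list or correlation reversed its sign in any setting run for it. Testing every probe set kept the one with the smallest p of each gene, so a conflicting probe set could hardly appear there. Some had the opposite sign, such as those of Slfn1 in RORγt deficiency (-0.13) and Igfbp7 under digoxin in wildtype cells (0.17). The signs of the other called genes were not followed across settings. The median of the Th1 list under digoxin in wildtype cells went from 0.03 to -0.00284 without wildtype DMSO array 1. Counts of called genes below follow the order RORγt deficiency in DMSO, digoxin in wildtype cells, digoxin in RORγt-deficient cells, difference of the digoxin effects and RORγt deficiency under digoxin, with 191, 22, 1, 0 and 1 (limma, 562 at an unadjusted p under 0.05 for the 0) as reported. Testing every probe set gave 225, 22, 1, 0 and 1, a common median 196, 22, 1, 0 and 1, the probe set of highest recovered level 221, 24, 1, 0 and 1, and a filter at a recovered level of 4, which kept 12542 genes, 230, 25, 1, 0 and 1. Quantile normalisation gave 4 (1 higher, against 51 of 191), 3 (0 higher, against 13 of 22), 0, 0 and 0, the last 3 with 140, 287 and 318 genes at an unadjusted p under 0.05. By its construction it gave the wildtype DMSO arrays, which centring had narrowed to an SD of 0.09, the spread of the others. It also ranked differences, not levels, which narrows changes between values at one end of the ranking, such as those of Il17a in RORγt-deficient cells. Array weights gave 224, 35, 1, 1 and 1, the wildtype DMSO arrays receiving the highest weight (1.34). A fit of the compared groups alone, with fewer degrees of freedom, gave 95, 9, 1 and 1 and was not applicable to the difference of the digoxin effects. The 2-fold threshold left 47, 14, 1, 0 and 1. A variance trend on the recovered level gave 241, 49, 0, 0 and 28, with 567 and 524 at an unadjusted p under 0.05 for the counts of 0, and the cause was not tested. Within a range of lowest level the recovered level followed a gene's own spread, so these counts do not isolate a dependence on intensity. Leaving out an array, with the lone remaining array assumed to vary like the other groups, gave from 17 to 56, 6 to 16, 1 to 1, 0 to 1 and 0 to 2 genes. The replicate number as a block gave 181, 25, 1, 0 and 2, the latter Il17a and S100a6, and the cause of the change was not tested. The numbers were not taken to pair the arrays, since the labels do not say that they do and deviations from the group means correlated at -0.242, -0.19 and -0.136 between wildtype DMSO and the other groups and at 0.325 to 0.454 among those, the latter a hint from the data and not from the design. With the wildtype DMSO numbers exchanged, the block gave 414, 60, 1, 2 and 27, the 2 being Iyd and Plac8. The correlation of RORγt deficiency and digoxin across genes (r = 0.671) was 0.671 at a common median, 0.658 after quantile normalisation, 0.682 with probe sets by recovered level and between 0.467 (without wildtype digoxin array 2) and 0.749 (without wildtype DMSO array 1) with an array left out, and the cause of this spread was not tested. Of the 31 list calls by camera, 31 passed under the block, 30 with probe sets by recovered level, 14 by fry and 0 with an estimated correlation, and 124 of 152 held when an array was left out. Of the calls of genes named by the rule, 61 of 140 for RORγt deficiency and 38 of 76 for digoxin in wildtype cells held with an array left out. The odds ratio for genes near the gene encoding RORγt lay between 1.01 and 3.49 over its alternatives, with the smallest p, 0.0618, for probe sets by recovered level. A filter on dim probe sets and an intensity trend were not run, because centred values carry no intensity, and the choice of probe set by suffix was already the one reported. Signal over background was not known beyond the recovered ranges, and the lowest level of 5651 genes lay between 2 and 4, where weak signals limit what could be detected.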

Other observations

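The comparison of RORγt-deficient cells in DMSO with wildtype cells in digoxin, and the genes named for it, were chosen after the results had been seen.

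Set directly against wildtype cells in digoxin, RORγt-deficient cells in DMSO had higher expression of S100a4 (1.67 ± 0.17, adjusted p = 0.0367), S100a6 (1.27 ± 0.14, adjusted p = 0.0367) and Tnfsf4, the gene of the costimulatory OX40 ligand (0.90 ± 0.10, adjusted p = 0.0412). These 3 were the genes called by limma, and 1032 had an unadjusted p under 0.05. All 3 were also called for RORγt deficiency in DMSO. S100a4 stood at -0.63 and -0.20 on the wildtype digoxin arrays, at 1.32 and 1.18 on those of RORγt-deficient cells in DMSO and at 1.13 and 0.76 on those of RORγt-deficient cells in digoxin. S100a4 and S100a6 lie within 10 Mb of the gene encoding RORγt. The calls rested on every array of the comparison: limma called 0 genes without RORγt-deficient DMSO array 1 or array 2 (1350 and 918 at an unadjusted p under 0.05), S100a6 alone without wildtype digoxin array 1 and S100a4 alone without wildtype digoxin array 2.

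Cell cycle genes separated RORγt deficiency from digoxin, with a median of -0.57 over 20 members and 14 called when adjusted over the list alone (camera adjusted p = 1.1e-17, and adjusted p = 0.214 with an estimated correlation). With an array left out that median lay between -0.68 and -0.43. Targets of p53 had a median of 0.41 over 13 members, 11 of them called when adjusted over the list alone (camera adjusted p = 1.1e-17, and adjusted p = 0.0548 with an estimated correlation), and between 0.37 and 0.43 with an array left out. Activation genes (0.18 over 16 members, camera adjusted p = 0.000721, and adjusted p = 0.344 with an estimated correlation) and naive T cell genes (0.11 over 12 members, camera adjusted p = 0.00353, and adjusted p = 0.214 with an estimated correlation) had 0 members called by limma on either count. Immediate early genes had a median of 0.16 over 14 members, with 1 called when adjusted over the list alone (camera adjusted p = 0.0142, and adjusted p = 0.624 with an estimated correlation). Th17 effectors had a median of 0.06 over 11 members and did not pass camera (adjusted p = 0.52).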
